A study of Mus musculus with 16 samples.

How the data were processed

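The study measured chromatin solubility by 4f-SAMMY-seq, in which nuclei are treated with DNase I and the chromatin is separated into fractions, each sequenced as its own library. The series holds a DNase-sensitive fraction (S2S, euchromatin) and a DNase-resistant fraction (S3, heterochromatin). No other fraction is among its libraries. Per the labels, 16 libraries from 8 groups of mouse cells belong to the series, 7 from neural progenitor cells (NPCs) and 9 from primary neurons. All carry batch 1. Each cell type was transduced with a lentivirus that carried Mecp2 or EGFP. The NPC groups hold 2 libraries each, except the S3 fraction with Mecp2, which holds 1. The neuron groups hold 3 S3 libraries and 2 S2S libraries with EGFP, and 3 S3 libraries and 1 S2S library with Mecp2.

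The processed values are 4 lists of genes from 2 comparisons made by the authors. They hold no value for any single library, so no replicate error, no depth and no paired fit could be computed, and every p-value below measures how genes and loci are placed on the genome and not the spread between cultures. Per the submitters' processing notes, FastQC, Trim Galore, Trimmomatic, BWA, deepTools and ChIPseeker were used with the mm10 assembly. Their versions, settings and roles, the way replicates were combined and the rule for calling a region are not given in the sources used here.

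For NPCs with Mecp2 against NPCs with EGFP, each row of the deposited tables pairs a gene with a region of 150 kb, the kind of overlap and a ratio change. The ratio change is a score that the authors deposited without a definition. It is above 0 in the list named as S2S to S3 and below 0 in the list named as S3 to S2S, and no deposited size lies under 0.1. For 70 of the 72 regions of the second list, 30 times the value has no more than 6 decimals. The direction from EGFP to Mecp2 is read from the names of the lists. Starts were written 1-based. Because regions are listed by their genes, a region without any gene would not appear. The tables call an overlap partial for most genes: 288 of the 356 such rows that could be set against the annotation have the gene wholly inside the region.

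For NPCs against neurons, the authors deposited 2 lists of gene symbols with no position or value, named as S2S to S3 and S3 to S2S. The names do not settle from which cell type the shift is counted, nor which viral arms entered. These lists are therefore given by name, with no direction between the cell types.

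Symbols were matched to the RefSeq annotation of GRCm38.p6, the assembly that mm10 stands for, by symbol or by a synonym that belongs to 1 gene. Of the distinct symbols, 3 of 3, 376 of 486, 3410 of 4568 and 3181 of 4186 matched in the order S2S to S3 and S3 to S2S for Mecp2, then for the cell types. Of symbols other than placeholders such as Gm numbers and Rik clones, 97.5% matched in the longer Mecp2 list, 96.5% in the cell type S2S to S3 list and 98.6% in the cell type S3 to S2S list; of the placeholders 38.6%, 55.3% and 47.0% matched in the same order. The test of the set of predicted and unnamed genes, which such symbols make up, is therefore void and is not reported, though the set stays among those over which p-values were adjusted. The loss also lowers the expected numbers of sets of named genes over all classes, so these were tested again without placeholders. The background was the 49509 genes on 21 chromosomes of the 20 annotation classes that the lists hold, or its 21887 protein-coding genes. A locus is a run of listed genes that neighbour each other in this annotation.

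Overlaps between lists, and 32 gene sets fixed before the data were examined, were tested by moving one list around the annotation order through every circular shift, which keeps its clustering. This exact shift test is two-sided, and the expected number is n1 × n2 / N. Sets had at least 3 members. Adjusted p-values are Benjamini-Hochberg values over the sets within a list, or over the 4 overlaps, with a threshold of 0.05. Shares of a set in 2 lists were compared by Fisher's exact test, two-sided and adjusted over the comparisons made. Direction was compared between experiments by Fisher's exact test on loci. Loci were counted beside those of 1000 random draws of genes, as a description. Gene length was compared by all circular shifts for protein-coding genes only: the planned comparison over all classes is void, because under 80% of the symbols of each longer list have an annotated length.

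Before use, the shift test was run on randomly placed copies of the lists. It called 2.34% of 640 tests for the longer Mecp2 list and 2.19% for the cell type S2S to S3 list over 49509 genes, where Fisher's exact test called 8.59% and 19.4%. The copies were themselves circular shifts, which the test enumerates, so its low share follows by construction and is no independent check. Sets of 200 scattered genes planted in the cell type S2S to S3 list at 2, 4 or 8 times their expected number were recovered in 100% of 50 simulations each. Recovery of smaller or clustered sets, or in the longer Mecp2 list, was not tested. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

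Genes named in the text follow a rule fixed in advance: all genes of a list of up to 15, up to 4 members of each called set and of 13 sets of main interest, the first 8 genes in alphabetical order of an overlap, the 10 regions with the largest change, and the 3 largest loci of a list without values with up to 4 genes each. Names outside it were chosen after the lists were seen, and are marked so. Alternatives fixed in advance were other backgrounds, other tests, lists without multigene arrays, without the fullest chromosome or reduced to loci, and the 50% of regions with the larger change. A comparison of neurons with Mecp2 against neurons with EGFP was not analysed here.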

Results

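Chromatin of mouse NPCs from the cortex of E13.5 embryos and of primary neurons from E18.5 embryos was fractionated by DNase sensitivity 5 days after lentiviral transduction with Mecp2 or EGFP. MeCP2 is a methyl-CpG binding protein whose dosage is tightly limited in the brain. NPCs received virus at a multiplicity of infection of 10 and neurons at 5, and 200000 cells entered each fractionation. S2S denotes the DNase-sensitive euchromatin fraction and S3 the DNase-resistant heterochromatin fraction. The series holds 16 libraries, and the values are the authors' lists of genes in regions that moved between the fractions, so sequencing depth is unknown and no value has a replicate error.

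The first comparison asks which genomic regions change fraction when NPCs receive extra Mecp2. The change ran almost wholly towards the euchromatin fraction: 72 regions of 150 kb with 486 genes were listed as S3 to S2S, against 1 region with 3 genes listed as S2S to S3. The single region of the opposite direction lay inside the body of Robo2, which encodes an axon guidance receptor, at chromosome 16, 74250001 to 74400000 on mm10. Its ratio change was 0.119 in the authors' deposited table, and it also held the microRNA gene Mir691 and had the pseudogene Gm18021 at its edge. The authors' deposited table gives the 72 regions a median ratio change of -0.106, from -0.100 to -0.140, and 51 of them lie between 0.1 and 0.11 in size. The scale of this ratio is not defined in the sources used here, and NPCs with Mecp2 have only 1 library of the S3 fraction.

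The region with the largest change was on chromosome 4, 153300001 to 153450000, over part of the adherens junction gene Ajap1, with a ratio change of -0.140 in the authors' deposited table. It was followed by a region next to Igsf21, a synaptic adhesion gene, on chromosome 4 from 140250001 to 140400000 at -0.135, which the authors' deposited table also links to Gm9867, Gm13016 and Gm13017. The whole of Bmp7, a bone morphogenetic protein of dorsal patterning, lay in a region at chromosome 2, 172800001 to 172950000, and Pmepa1, a TGF-beta pathway inhibitor gene, was cut by the region at 173250001 to 173400000 of the same chromosome. Their ratio changes were -0.131 and -0.123 in the authors' deposited table. A region of chromosome 4 from 131400001 to 131550000 held only Gm831 and had a ratio change of -0.129 in the authors' deposited table. The body of Rbfox3, which encodes the neuronal nuclear antigen NeuN, contained the region at chromosome 11, 118650001 to 118800000, at -0.128 in the authors' deposited table. Ksr2 and Nos1, the neuronal nitric oxide synthase gene, shared a region at chromosome 5, 117750001 to 117900000, with -0.119 in the authors' deposited table.

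The last 3 of the 10 regions held more genes. Chromosome 10 from 79950001 to 80100000 held 11 genes, among them Arid3a, the NMDA receptor subunit gene Grin3b, the lipid transporter gene Abca7, Polr2e and Gpx4, with -0.117 in the authors' deposited table. Chromosome 2 from 91050001 to 91200000 also held 11 genes, among them Spi1, the myeloid transcription factor PU.1, the cardiac gene Mybpc3, Madd and the liver X receptor gene Nr1h3, with -0.116 in the authors' deposited table. Tmem179 lay at the edge of a region of 6 genes at chromosome 12, 112350001 to 112500000, with -0.115 in the authors' deposited table. Per region, the listed genes numbered 6 in the median and 19 at most, and 306 of the gene identifiers were protein-coding, 43 lincRNA, 40 antisense and 23 microRNA genes by the file's own classes. The regions lay on 16 chromosomes, with none on 3, 18, 19, X or Y, and 6 pairs of them touched.

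**Figure D1:**
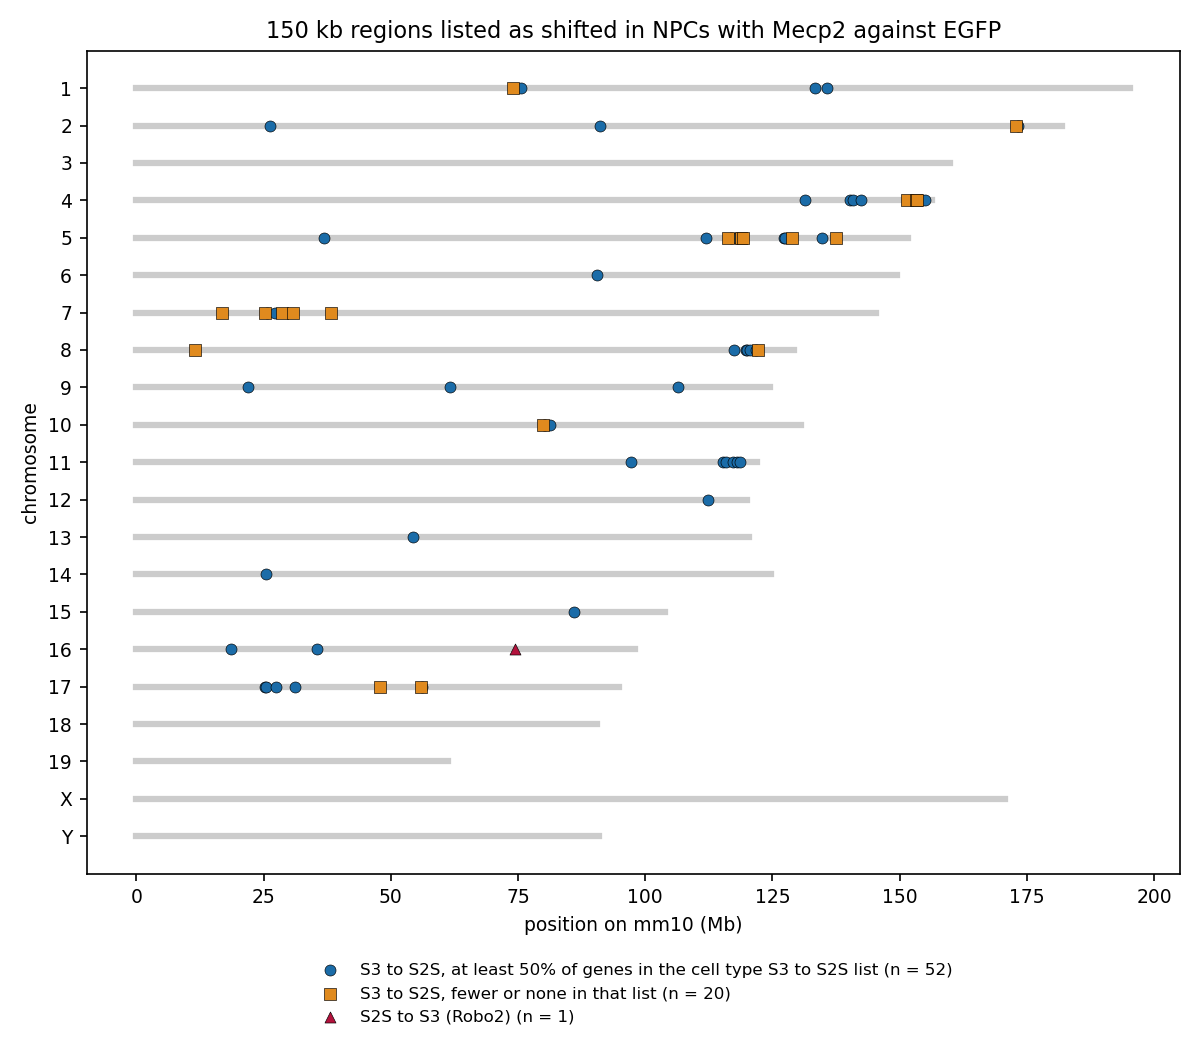
Positions of the 73 regions listed as shifted in NPCs with Mecp2 against EGFP, with the chromosome on the vertical axis and the position on mm10 in Mb on the horizontal axis; grey bars run to the end of the last annotated gene. Circles and squares are the 72 regions listed as S3 to S2S, split by whether at least 50% of their genes are also in the cell type list S3 to S2S (52 and 20 regions), and the triangle is the region in Robo2.

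No functional group of genes was over-represented in the 72 regions by the exact shift test, which compares a list with all its shifts along the gene order. Of 32 sets, 0 had more members than expected after adjustment, and 2 did at an unadjusted p under 0.05, the glial set and the muscle and heart set. Fisher's exact test, which takes neighbouring genes as independent, called the muscle and heart set alone. Of 34 neural progenitor markers the list held Hes5, a Notch effector (1 against 0.258 expected, exact adjusted p = 1). Of 36 pan-neuronal markers it held Rbfox3 and the neuronal RNA-binding protein gene Elavl3 (2 against 0.273, exact adjusted p = 0.433). Bmp7 and Tgfb1 were the 2 of 95 morphogen ligands and antagonists (0.721 expected, exact adjusted p = 1), and Tbx1 was the 1 of 189 developmental transcription factors (1.44 expected, adjusted p = 1). The astroglial gene Aldh1l1 and the myelin gene Mag (2 of 24), the neutrophil elastase gene Elane (1 of 29 microglia and blood genes) and Actl6b, the neuronal SWI/SNF subunit (1 of 30 SWI/SNF genes), were listed as well. None of these passed the shift test, nor did the 3 muscle and heart genes, with an exact adjusted p of 0.374. No member was listed for the synaptic set of 77 genes, GABAergic and ventral forebrain genes, Hox genes, vascular and mesenchymal markers, MeCP2 and its partners and known targets, or Polycomb and trithorax proteins. The expected number was 0.585 for the synaptic set and lower for each of the others, so these counts of 0 show no depletion. Grin2c, Grin3b, Grm4 and Cacna1h, receptor and channel genes outside the synaptic set, were listed. The names other than Grin3b were chosen after the lists were seen. Predicted and unnamed genes made up 34.2% of the listed symbols; the test of this set is void in every longer list, because only 38.6% to 55.3% of such symbols matched the annotation.

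The second comparison asks which regions differ between NPCs and neurons. The authors' list named as S2S to S3 held 4568 genes and the list named as S3 to S2S held 4186, with 3 symbols in both (BC048671, Cyp2t4 and Gm44640, named after the lists were seen). The list names do not settle from which cell type the shift is counted. The 2 lists differed in kind: 44.6% of the matched genes of the S2S to S3 list were protein-coding, against 66.5% in the S3 to S2S list.

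Chemosensory receptor genes were over-represented in the S2S to S3 list. It held 689 of 1428 olfactory receptor genes and pseudogenes (Olfr1, Olfr1028, Olfr1029 and Olfr1030 among them), 7.01 times the 98.4 expected, with an exact adjusted p of 3.232e-04. It held 221 of 424 vomeronasal, formyl peptide and taste receptor genes, such as Fpr-rs3, Fpr-rs4, Fpr-rs6 and Fpr-rs7, 7.57 times the 29.2 expected (exact adjusted p = 3.232e-04). Liver-type detoxification and protease inhibitor families, with Cyp2a12 and Cyp2b13, added 70 of 230 genes against 15.8 expected (exact adjusted p = 5.171e-04). Of the clustered protocadherins, cell surface proteins of neuronal self-recognition, 33 of 58 were listed, all from the alpha and beta clusters, against 3.99 expected. They form a single stretch of chromosome 18, and the set did not pass the shift test (exact adjusted p = 0.125), while Fisher's exact test, which takes its genes as independent, called it (adjusted p = 7.901e-23).

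Of the fixed set of 189 developmental transcription factors the list held none, where 13.0 were expected (exact adjusted p = 3.232e-04), and none of 90 ribosomal protein genes, where 6.20 were expected (adjusted p = 0.0185). The ribosomal call was lost without multigene arrays (exact adjusted p = 0.193) and without chromosome 7 (exact adjusted p = 0.0748). Small non-coding RNA genes numbered 18 against 91.3 expected (exact adjusted p = 8.618e-04), with Mir101c, Mir1899, Mir1906-2 and Mir195b among them. By annotation class the list held 18 of 1228 microRNA genes, 62 of 1340 snoRNA genes and 62 of 1004 snRNA genes, so the call concerns mainly microRNA genes. Of the pan-neuronal and synaptic sets it held Tbr1, a cortical transcription factor gene, and the glutamate receptor genes Gria4 and Grm5, and its 1 gene of the morphogen set was Fgf14. No progenitor marker was listed, against 2.34 expected, a set that did not pass (exact adjusted p = 0.412). Predicted and unnamed genes were 53.0% of the listed symbols.

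Developmental gene sets were over-represented in the S3 to S2S list when all gene classes formed the background. Morphogen ligands and antagonists numbered 22 of 95 against 6.10 expected (exact adjusted p = 4.309e-04), with Bmp1, Fgf1, Fgf11 and Fgf15 first in set order. The set was picked by gene symbol, so not every member need act as a morphogen. The call held among protein-coding genes, with 9.18 expected and an exact adjusted p of 0.00623. Hox genes, which pattern the body axis, numbered 17 of 39 against 2.51 expected (exact adjusted p = 0.00743), all from the Hoxa and Hoxc clusters, as Hoxa10, Hoxa11, Hoxa13 and Hoxa3. Developmental transcription factors numbered 27 of 189 against 12.1 (exact adjusted p = 0.00194), with Gata5, Tbx1, Foxc2 and Foxf1. Neural progenitor markers numbered 7 of 34 against 2.18 (exact adjusted p = 0.0297), with Nes, Hes1, Hes5 and Neurog1. Immediate early genes numbered 6 of 24 against 1.54 (exact adjusted p = 0.0297), with Jund, Egr3, Arc and Nr4a1, and solute carriers 48 of 399 against 25.6 (adjusted p = 0.00582), with the neuronal chloride exporter gene Slc12a5. Against protein-coding genes alone these 5 calls were lost, at 4.51 times the expected number for Hox genes (exact adjusted p = 0.124), 2.59 times for immediate early genes (exact adjusted p = 0.212), 2.13 times for progenitor markers (exact adjusted p = 0.294), 1.48 times for developmental transcription factors (exact adjusted p = 0.308) and 1.25 times for solute carriers (exact adjusted p = 0.522). With placeholder symbols left out of lists and background, an alternative chosen after the data were seen, the same 5 calls were lost, with exact adjusted p from 0.142 to 0.507, and that of morphogens was kept (exact adjusted p = 0.0179).

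Pan-neuronal markers were also found in the S3 to S2S list, 6 of 36 (Rbfox3, Camk2b, Bcl11b and Neurod2 among them), against 2.31 expected (exact adjusted p = 0.139). The share of progenitor markers, 20.6%, and that of pan-neuronal markers, 16.7%, did not differ detectably (Fisher's exact p = 0.763). The list further held 7 of 77 synaptic genes (Grin1, Grik3, Kcnq2 and Cacna1d among them), Slc32a1 and Pvalb of the GABAergic set, Ncor2, Hdac3 and Gprin1 of the MeCP2 set, and the Polycomb genes Cbx2, Cbx4 and Cbx8. None of these sets passed, with exact adjusted p of 0.723, 1, 0.617 and 1. Members of sets for other cell types were listed too: C1qa, C1qb, C1qc and Tyrobp of 29 microglia and blood genes (exact adjusted p = 0.474), Aldh1l1 and Opalin of the glial set (adjusted p = 1), and Thy1 of the vascular and mesenchymal set (adjusted p = 1). Thy1 is also in the pan-neuronal set and is already counted among its 6 listed members. Small non-coding RNA genes, a set of microRNA and small nucleolar RNA symbols, numbered 166 against 85.2 expected (exact adjusted p = 4.309e-04). This call was lost without placeholder symbols (exact adjusted p = 0.214). By annotation class the list held 165 of 1228 microRNA genes, 23 of 1340 snoRNA genes and 30 of 1004 snRNA genes, so the excess was one of microRNA genes. Olfactory receptors were absent, where 91.8 were expected (exact adjusted p = 0.00207), and the sweet taste receptor gene Tas1r2 was the 1 member of the vomeronasal and taste set, where 27.2 were expected (adjusted p = 0.00743). Predicted and unnamed genes were 43.7% of the listed symbols.

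**Figure D2:**
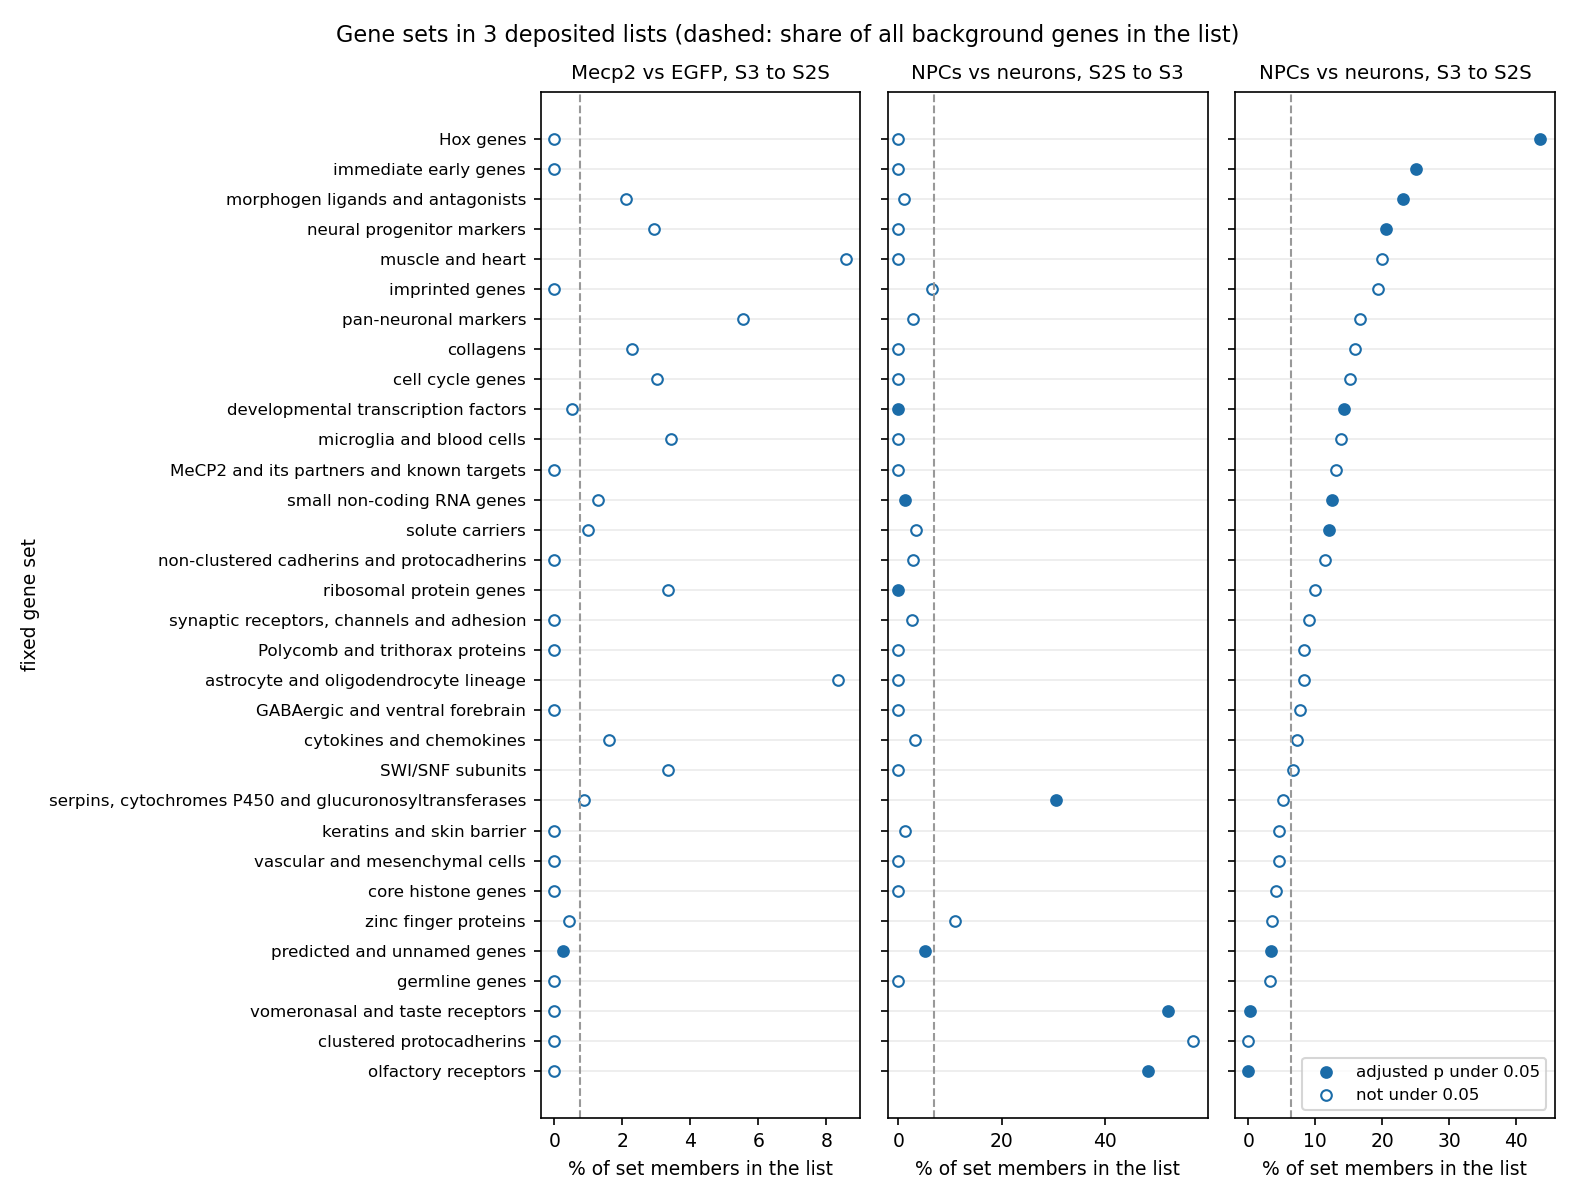
Share of the members of each of the 32 fixed gene sets, in percent on the horizontal axis, that lie in the list Mecp2 against EGFP, S3 to S2S (left), and in the lists NPCs against neurons, S2S to S3 (middle) and S3 to S2S (right). Filled points have an adjusted p under 0.05, except that the test of predicted and unnamed genes is void, and the dashed line is the share of all background genes; Hox genes reach 43.6% in the right panel and olfactory receptors 48.2% in the middle one.

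The difference between the 2 cell type lists was itself tested, for sets called in at least 1 of them. The set of developmental transcription factors made up 0.849% of the S3 to S2S list and 0% of the S2S to S3 list (Fisher's exact test, adjusted p = 8.726e-09). By the same exact test the S3 to S2S list also had the larger share of Hox genes (adjusted p = 9.603e-06), morphogens (adjusted p = 4.118e-06), progenitor markers (adjusted p = 0.0104), immediate early genes (adjusted p = 0.0203) and ribosomal protein genes (adjusted p = 0.00256). Olfactory receptors made up 20.2% of the S2S to S3 list and 0% of the other (Fisher's exact test, adjusted p = 1.696e-212). Among protein-coding genes the differences in progenitor markers and immediate early genes were lost (0% against 0.331% and 0.284%, Fisher's exact test, both adjusted p = 0.0754), and the others named here were kept, with an adjusted p of at most 0.0238. This test takes genes as independent, which neighbouring genes are not.

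The longest run of the S2S to S3 list had 97 genes at chromosome 2, 87149720 to 88592726, and began with Olfr1111, Nlk-ps1 and Olfr1112, and the next were runs of 42 genes at chromosome 2, 36301541 to 37332732, from Olfr335-ps, and at chromosome 9, 19248357 to 20385182, from Olfr843. In the S3 to S2S list the longest run had 25 genes at chromosome 15, 76150279 to 76501155, with Plec, the cytolinker gene, and Parp10. A run of 23 genes at chromosome 3, 87966758 to 88362338, held the progenitor intermediate filament gene Nes with Bcan and Hapln2, which encode brain matrix proteins. Another run of 23 genes at chromosome 10, 79960152 to 80294114, began with Wdr18 and Grin3b and overlapped 2 of the regions listed for Mecp2. Chromosome X had 104 loci in the S2S to S3 list and 0 of the 1076 loci of the S3 to S2S list (Fisher's exact p = 9.168e-42); the S2S to S3 list held 88 of the 966 X protein-coding genes (9.11%), against 6.95% of all protein-coding genes. Chromosomes 11 and 15 leaned the other way, with 118 and 77 loci in the S3 to S2S list and 17 each in the S2S to S3 list (Fisher's exact p = 1.938e-14 and 5.452e-07). These 3 chromosomes were chosen after the lists were seen, and the tests take the loci of a chromosome as independent.

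**Figure D3:**
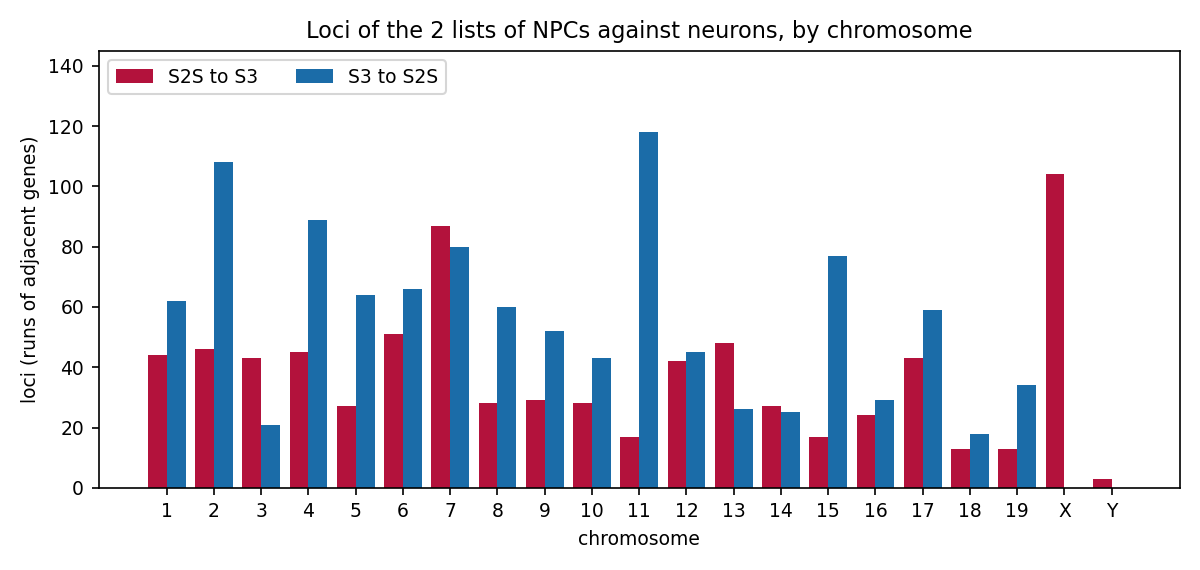
Number of loci, that is runs of neighbouring listed genes, on each chromosome in the 2 lists of NPCs against neurons; the vertical axis counts loci from 0 and the horizontal axis gives the chromosome. Chromosome X has 104 loci listed as S2S to S3 and none listed as S3 to S2S.

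Set against each other, most genes listed as S3 to S2S for Mecp2 in NPCs were also in the cell type S3 to S2S list. Of the 486 genes listed for Mecp2 as S3 to S2S, 331 (68.1%) were in the cell type S3 to S2S list and 4 in the cell type S2S to S3 list. The first 8 shared genes in alphabetical order were Abca7, Abcg1, Abhd14a, Abhd14b, Acot7, Acp2, Acy1 and Adamtsl5. Of the matched genes 256 were shared, 10.6 times the 24.2 expected from n1 × n2 / N, with an exact adjusted p of 1.616e-04. Among protein-coding genes 202 were shared against 28.7 expected (exact adjusted p = 3.655e-04). Both expected numbers take in genes of any starting fraction, which the lists do not give. By region, 32 of the 72 had all their genes in the cell type list, 54 had at least 1 and 18 had none; Ajap1 and Bmp7 were in regions with none. Regions with at least 50% of their genes in that list had a mean ratio change of -0.108 ± 0.00775 (SD over 52 regions) and the rest -0.109 ± 0.00998 (SD over 20 regions) in the authors' deposited table, which did not differ detectably (permutation p = 0.490, two-sided). Robo2, Mir691 and Gm18021 were in neither cell type list.

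The overlap with the cell type S2S to S3 list was smaller than expected, with 3 matched genes against 25.9 (exact adjusted p = 0.0281). The shared symbols were Cyp2t4, Ebi3, Zfp119b and Gm44640. The 2 cell type lists have only 3 symbols in common, so the 256 matched genes in the S3 to S2S list could hardly be in this one too. The expected number makes no allowance for this, so the smaller overlap is no result separate from the larger one. The main ratio was 0.116 times the expected number. With fewer genes tested the ratio was similar but not called, at 0.145 among protein-coding genes (exact adjusted p = 0.0833) and 0.135 in the regions with the larger change (exact adjusted p = 0.105). Of the protein-coding genes in the 72 regions 1.03% were in this list. In 1000 draws of windows with as many protein-coding genes the mean was 4.89%, and 6.8% of draws were as low as the regions. Gene density is therefore not excluded as a source of the smaller overlap, and these draws make no allowance for the larger one either. The NPC EGFP libraries may have served in both comparisons. The lists hold no values from which chance overlap through shared libraries could be simulated, so part of the excess may come from shared controls.

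The split between the named directions was set side by side for the 2 experiments. Counted in loci, 98.2% of the Mecp2 changes (110 of S3 to S2S against 2) and 58.0% of the cell type changes (1076 against 779) were named S3 to S2S, an odds ratio of 39.8 (Fisher's exact p = 1.369e-22, two-sided). Loci cut from the same region are not independent, and the single Robo2 region counts as 2; with up to 2 unlisted genes allowed within a locus, the Mecp2 lists had 67 loci against 1 and the odds ratio was 60.3 (Fisher's exact p = 4.737e-17). These p-values do not measure the spread between cultures, and the S3 fraction of NPCs with Mecp2 has only 1 library, so they do not show that the treatments differ. Because the names do not settle the direction between the cell types, the cell type lists were also turned, which was chosen after the data were seen; the share was then 42.0% and the odds ratio 76.0 (Fisher's exact p = 4.779e-37). Olfactory receptors made up 0% of the Mecp2 S3 to S2S list and 20.2% of the cell type S2S to S3 list (Fisher's exact test, adjusted p = 2.341e-34), while the shift test did not call their absence from the Mecp2 list, with 10.8 expected (exact adjusted p = 1). The cell type S3 to S2S list held 0 olfactory receptors as well. Between it and the Mecp2 S3 to S2S list, 0 of 9 sets differed in share, the void set left out (Fisher's exact test, lowest adjusted p = 0.339).

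A list made from regions of several genes must form fewer loci than as many single genes drawn at random, so the next counts describe the lists and test nothing. The 376 matched genes of the Mecp2 S3 to S2S list formed 110 loci where random draws of as many genes gave 373 on average. The cell type lists formed 779 loci against 3176 (S2S to S3) and 1076 against 2977 (S3 to S2S). Protein-coding genes of the cell type S2S to S3 list were short, with a median length of 3.73 kb against 17.2 kb in the background (exact adjusted p = 2.741e-04). Without multigene arrays, an alternative chosen after the data were seen, its median was 11.4 kb against 19.5 kb (exact adjusted p = 1.535e-04). The medians of the Mecp2 S3 to S2S list, 14.4 kb, and of the cell type S3 to S2S list, 14.96 kb, did not pass (exact adjusted p = 0.370 and 0.0910); without arrays the second, then 15.2 kb, did (exact adjusted p = 1.535e-04).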

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

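No paired analysis was possible because the deposited lists hold no values of single libraries; for the same reason no library could be left out and depth could not be related to any result. Alternatives were fixed before the data were examined, except lists and background without placeholder symbols, the turned cell type lists and gene length without arrays, which were chosen after seeing the data. Over 116 alternative values of the main results, 92 kept their direction and their side of the threshold or stayed within 1.5 times the count, 0 reversed, and the rest follow. Over 233 values of single gene sets, 214 kept both, 14 lost their call, 2 gained one and 3 reversed. Not all of these values could change: the 6 alternatives for each overlap of the 3-gene Mecp2 list had 0 shared genes throughout. The counts of loci beside random draws test nothing, and sets with few expected members could hardly gain a call. The tallies are therefore no measure of robustness. Gene counts fell by construction, and settings that need a position or class were set against the matched genes. Protein-coding genes numbered 1 in the Mecp2 S2S to S3 list, 1521 in the cell type S2S to S3 list and 2115 in the cell type S3 to S2S list; loci numbered 110 in the Mecp2 S3 to S2S list and 779 and 1076 in the cell type lists; and 0 genes of the Mecp2 S2S to S3 list were left without its fullest chromosome. The regions with the larger change held 272 genes. The overlap of the Mecp2 S3 to S2S list with the cell type S2S to S3 list was no longer called among protein-coding genes (0.145 times the expected number) and in the regions with the larger change (0.135 times), where fewer genes were tested. Counts of called sets include the void set of predicted and unnamed genes. They went from 0 more and 1 fewer to 1 and 2 with Fisher's exact test in the Mecp2 S3 to S2S list, and to 0 fewer among protein-coding genes and without placeholders, where the void set has lost its call or has no member. In the cell type S2S to S3 list they went from 3 more and 4 fewer to 5 and 7 with Fisher's exact test, to 2 fewer among protein-coding genes, where small non-coding RNA genes have no member, and without multigene arrays to 0 more, since the 3 called sets are themselves arrays, and to 2 fewer, as the ribosomal call was lost and the void set turned. In the cell type S3 to S2S list 7 sets with more members became 1 among protein-coding genes, with 5 calls lost and small non-coding RNA genes not testable, and 1 without placeholders, with 6 calls lost; 3 with fewer became 1 without arrays. Predicted and unnamed genes of the cell type S2S to S3 list turned from fewer to more than expected among protein-coding genes (1.21 times), without arrays (1.05 times) and with 1 gene per locus (1.09 times), but its test is void, since 55.3% of its placeholder symbols matched. The shorter length of the cell type S3 to S2S genes, 0.871 of the background median (adjusted p = 0.0910), was called when genes were permuted as if independent (permutation, adjusted p = 3.000e-04) and without multigene arrays, at 0.778 of the background median (exact adjusted p = 1.535e-04); the cause was not tested. Over their alternatives the adjusted p ranged from 3.121e-08 to 0.105 for the overlap of the Mecp2 S3 to S2S list with the cell type S2S to S3 list, from 7.041e-212 to 7.999e-04 for the overlap with the cell type S3 to S2S list, from 4.332e-10 to 0.142 for Hox genes, from 5.252e-04 to 0.308 for developmental transcription factors, from 0.0166 to 0.294 for progenitor markers, from 1.864e-15 to 0.214 for small non-coding RNA genes and from 6.242e-07 to 0.0179 for morphogens of the cell type S3 to S2S list. In the cell type S2S to S3 list it ranged from 0.00640 to 0.193 for ribosomal protein genes and from 7.901e-23 to 0.398 for clustered protocadherins. A stricter overlap of regions was not run, since only the Mecp2 lists hold coordinates and they share none.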

Other observations

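The tests of shared NPC EGFP libraries, of an even offset, of the number of libraries and of the X chromosome were chosen only after the result was seen. Other groups of the cell type S3 to S2S list, none of which passed, included 7 of 35 muscle and heart genes (Tnnt2, Tnni1, Tnnc1, Myl2, Myl3, Myl7 and Mybpc3; exact adjusted p = 0.123), of which Tnnt2, Tnni1 and Mybpc3 were the 3 in the Mecp2 list. They also included 6 of 31 imprinted genes (H19, Mest, Cdkn1c, Phlda2, Slc22a18 and Airn; exact adjusted p = 0.225), 7 of 44 collagens (adjusted p = 0.180) and the replication genes Mcm2, Cdc6, Cdt1 and Rrm2 with Cenpa, 5 of 33 cell cycle genes (adjusted p = 0.226). The imprinted genes of the S2S to S3 list were Snrpn and Mkrn3. These names were chosen after the lists were seen.

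Sets that passed in no list over all classes were further zinc finger proteins (2 in the Mecp2 S3 to S2S list, 49 in the cell type S2S to S3 list and 16 in the cell type S3 to S2S list), cytokines and chemokines (2, 4 and 9 in the same order), keratins and skin barrier genes (0, 2 and 7), core histone genes (0, 0 and 4), non-clustered cadherins (0, 1 and 4) and germline genes (0, 0 and 1). Among protein-coding genes, zinc finger proteins of the cell type S3 to S2S list were fewer than expected, 13 against 41.1 (exact adjusted p = 0.00623).

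The first pattern is that genes listed as S3 to S2S with Mecp2 lie in the cell type S3 to S2S list. Gene density as the cause is argued against: of the protein-coding genes in the 72 regions 68.7% were in that list, where 1000 draws of windows with as many protein-coding genes gave 10.1% ± 4.36 (SD) and at most 24.7%. The draws were not matched for the fraction in which a window starts, which the lists do not give. Chance values of shared NPC EGFP libraries cannot be told apart from a shared change. They could fill one cell type list and empty the other. The overlap with the opposite list was 0.116 times the expected one, but the cell type lists share only 3 symbols. A large overlap with one therefore lowers that with the other, and the ratio decides nothing. Chance values would act in this direction only if the cell type shift is counted from NPCs. Read as the Mecp2 names were, the cell type names would count it from neurons, though the names do not settle this. A hypothesis that Mecp2 moves NPC chromatin along the axis that separates the cell types stays open and untested.

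The second pattern is the 1 region against 72 in the Mecp2 comparison. One offset of the ratio in all windows with even noise is argued against only if every window with a gene could be called alike. The regions held 3 protein-coding genes in the median, and 1000 random draws of 72 windows with a gene gave medians from 1 to 2. The rule for calling a region is not given, so an offset under a rule that depends on the starting ratio was not tested. An offset that grows with gene content was not tested. With 1 library of the S3 fraction for NPCs with Mecp2, deviations of that library may also pass as shifts, and the number of libraries cannot be told apart from the treatment. An effect of Mecp2 itself, which the design names, stays open.

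The third pattern is that X chromosome genes are in one cell type list only. The 6 multigene array sets do not account for it, since 102 of the 104 X chromosome loci of the S2S to S3 list were left without them. This could hardly come out otherwise, because 949 of the 966 X protein-coding genes lie outside these sets. Other gene families that form arrays on X were not tested. An offset of the whole X chromosome between the cell types cannot be told apart from separate changes of X regions: of the X protein-coding genes outside the arrays 9.06% were in that list, above the other chromosomes, but the 7.92% of chromosome 7 did not differ detectably from it (Fisher's exact p = 0.330). A hypothesis that X chromatin changes between progenitors and neurons stays open and untested. Embryonic day and multiplicity of infection go with cell type and cannot be told apart from it. The sex of the embryos is not among the labels used here, so it could not be taken into account.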
